A study of Drosophila melanogaster
Mus musculus with 4 samples.

How the data were processed

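ATAC-seq libraries from B220+CD43+ cells of mouse bone marrow (C57BL/6, per the labels) were compared between 2 wild-type and 2 Hdac3-deleted samples; groups and replicate numbers came from the sample titles. The submitters' processing notes name Bowtie2 2.2.4, SAMtools, MACS2 2.0.10, DiffBind 1.10.2 and edgeR, and the genome builds mm10 and dm3, without giving their order or settings. Per the file headers, peaks were called in each library by itself with MACS2 2.0.10.20131216 without a control library, at a q cutoff of 0.001, without a fragment model, extending tags to 140 bp and keeping 1 tag per position. Also per the file headers, the reads given to the peak caller had been filtered for mapping quality and duplicates and shifted, as their name states. The headers give 99091070, 65177178, 80749696 and 46991458 tags for wild-type replicates 1 and 2 and Hdac3-deleted replicates 1 and 2, of which 70540115, 52188549, 57880292 and 36656102 were left after filtering.

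In the peak lists, the pileup is a signal, the number of fragments at the summit, which the authors did not scale between libraries, per the file headers. The peak score is a −log10 p-value or q-value against the background of the same library, per the file headers. The fold enrichment is a ratio of the pileup to that background, per the file headers; these values per peak are the authors' and were used only to describe and filter peaks within a list.

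The table of sites was made by the authors with 1 signal column per library (normalized reads per site). Its log2 columns hold the log2 of mean values per genotype and their difference (the fold), as tested on the deposited values. Its p-value and FDR columns are the authors' deposited results of their own comparison; values from them are named as such. How the authors merged peaks into sites is not given in the sources used here; each of the 69709 sites overlapped peaks of at least 2 libraries. Columns were matched to samples through the names of each sample's own peak file. Site positions are given as in the table; the start of 100% of the sites lay 1 bp before the start of a peak in the lists. The values of each library were whole multiples of the value of 1 read (0.664, 1.13, 0.999 and 1.33), for 100% of the values at a tolerance of 0.001 reads, which gave the reads per site. The smallest number of reads at a site was 3, 1, 1 and 1 in the 4 libraries and no value was 0. Duplicate reads without molecular identifiers are not independent molecules. No chromosome of Drosophila occurred in the site table or the peak lists (0 features), so the added S2 cells were not used for scaling.

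The planned test of counts was replaced, as laid down for a table that holds whole reads only after scaling, by limma 3.58.1 (R 4.3.3) on log2(value + 1), with the prior variance following the mean level and Benjamini-Hochberg adjustment at 0.05. A fold change is therefore on the log2(value + 1) scale and understates the change of low sites. The coefficient is Hdac3 deleted minus wild type, and the 4 libraries entered without covariates. The edgeR filter on low counts removed 0 sites, so no site was left out and the alternative of no filter is identical. On the recovered reads edgeR 4.0.16 (quasi-likelihood test, TMM factors) was run as an alternative and called 14618 sites; DESeq2 1.42.0 was another. Before the data were examined, the following alternatives were fixed: DESeq2 size factors, library totals, loess against abundance, the DESeq2 Wald test, the replicate block, each library left out, other thresholds and other peak cutoffs. With a library left out, the lone sample of its genotype is assumed to vary like the others. Scaling to the tags left after filtering, other pseudocounts, a filter at a mean of 50 reads, the edgeR fit and the crossed block were chosen after seeing the data, as were the windows, the blocks, the width classes and the sites low in 1 library.

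Named sites followed a rule fixed before the data were examined: per direction the 10 sites with the largest absolute log2 fold change among those past the threshold, with both Hdac3-deleted libraries on the same side of both wild-type libraries and a mean at or above the median site. The rule allowed 1 site per gene; with no mouse gene names used here this became 1 site per 100 kb. The planned gene lists, promoter and distal classes, antigen receptor loci and genes named in advance, Hdac3 itself among them, were not analysed here because they need a mouse annotation of mm10; the gene table at hand was of Drosophila. The deletion was therefore not checked at the Hdac3 gene.

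Windows of 1 Mb with at least 8 sites (1849 windows, 68246 sites) were tested with limma on the mean log2 value per library. Blocks were runs of at least 4 called sites with an absolute log2 fold change above 2, in the same direction and less than 200 kb apart. To test copy number, blocks were also sought in the difference of 1 library per genotype, as at least 4 such sites with a difference above 2 in size, and measured in the other 2 libraries, a choice made after seeing the data. Only those that matched a block found with all libraries were used. Peak lists were compared with bedtools 2.31.1, counting a peak as shared at an overlap of at least 1 bp, and Python 3.11.15. Replicates were compared before averaging: the correlation across sites, which are not independent replicates, was 0.969 for the wild-type pair and 0.959 for the Hdac3-deleted pair, against 0.871 to 0.918 between genotypes. A chi-square test of their reads gave 5.05 and 4.75 per degree of freedom within genotypes, more than counting error alone; this covers only counting error and does not show that the replicates came from separate mice. They were counted separately because the titles number them as replicates.

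The fits were tested on simulated data: reads were drawn for the 69709 sites from the measured means, with 50 sites changed at each size, for the comparison of Hdac3 deleted with wild type. limma recovered 2.00% of the sites changed 1.5-fold, 32.0% of those changed 2-fold, 98.0% of those changed 4-fold and 100% of those changed 8-fold, with 4 false calls. For the windows, 40 of 40 windows moved by 0.5 on the log2 scale were recovered, with 1 false call. In these simulations each site varied by itself, with a common dispersion, and the scaling between libraries was exact. Error shared by the sites of a window or a library was thus left out. The real tests, above all that of windows, may therefore give more false calls and recover less.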

Results

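Accessible chromatin was profiled by ATAC-seq, in which a transposase cuts open DNA and inserts sequencing adapters, in B220+CD43+ cells sorted from the bone marrow of mice 8 weeks old. B220 and CD43 together mark early B cell precursors, the stage at which immunoglobulin heavy chain genes are rearranged. The libraries came from 2 wild-type samples and 2 samples with Hdac3 deleted; Hdac3 encodes a histone deacetylase that works in nuclear corepressor complexes. Each library started from 50000 sorted cells to which 5% Drosophila S2 cells, a fly cell line, had been added. The reads counted in the 69709 sites of the mm10 genome came to 32988999 and 19017456 for wild-type replicates 1 and 2. They came to 21177343 and 16132402 for Hdac3-deleted replicates 1 and 2. The median site held 183, 108, 132 and 95 reads in these 4 libraries. The labels do not say that the replicates came from separate mice, so p-values measure the spread between these samples. In the Hdac3-deleted pair that spread may be technical. Wild-type replicate 2 had 10 peaks on chromosome Y below 50 Mb, and wild-type replicate 1 had 0. Replicate 2 also had 27 sites of chromosome X more than 8-fold below each other library. These values argue against both wild-type libraries coming from the same cells.

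The first comparison asked which accessible sites of these precursors differed when Hdac3 was absent. Of 69709 sites, 8133 were higher and 6202 were lower in Hdac3-deleted cells. Among the higher sites the median log2 fold change was 1.18, and among the lower sites it was -0.89. Changes above 3 on the log2 scale were found at 34 higher sites, and changes below -3 at 66 lower sites. The largest fall lay on chromosome 1 and the largest rise among the named sites on chromosome 9. These 14335 calls came from limma on log2(normalized reads + 1) with Benjamini-Hochberg adjusted p under 0.05, with 2 libraries per genotype; 22991 sites had an unadjusted p under 0.05. Scaling by library sets the median log2 fold change near 0 (it was -0.01) and the S2 cells were not used, so an overall shift could not be seen. Leaving out wild-type replicate 1 lowered the number of calls to 6595, leaving out Hdac3-deleted replicate 1 lowered it to 8506 with an even split (4235 higher, 4271 lower), and dividing the reads by the tags left after the authors' filtering gave 8742 (5784 higher, 2958 lower).

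**Figure D1:**
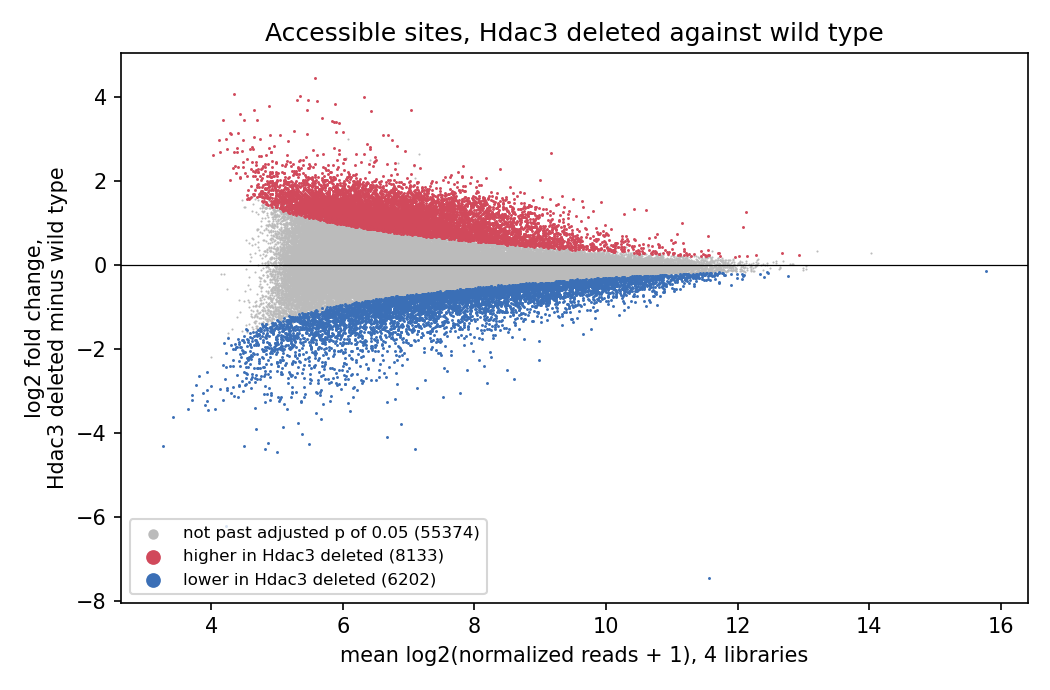
Each point is 1 of the 69709 sites, with the mean log2(normalized reads + 1) of the 4 libraries on the x axis and the log2 fold change, Hdac3 deleted minus wild type, on the y axis. Red points are the 8133 sites called higher and blue points the 6202 called lower; the single point near -7.45 is the site on chromosome 1.

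Sites that rose were named by size among the well covered ones. The largest rise was at chr9:79941518-79942188, from 36.4 ± 11.1 normalized reads in wild type to 474 ± 106 in Hdac3-deleted cells (SD, n = 2 each; log2 fold change 3.68, limma, Benjamini-Hochberg adjusted p = 2.03e-06). A site at chr9:77949708-77950231 rose by 2.71 on the log2 scale, from 47.4 ± 5.1 to 318 ± 53.2 reads (SD, n = 2). On chromosome 18, the chromosome that carries Hdac3, the site at chr18:41979003-41980036 went from 229 ± 31.5 to 1441 ± 126 reads (SD, n = 2; log2 fold change 2.65). Of the 8 other sites within 100 kb of it, 7 were also called higher and 0 lower, whereas around chr9:79941518-79942188 2 of 11 were higher and around chr9:77949708-77950231 2 of 17 were higher and 1 lower. The site at chr12:30377806-30378131 rose from 59.6 ± 16.7 to 308 ± 20.6 reads (SD, n = 2), and the 3 other sites within 100 kb were called higher too. Smaller rises, between 2.14 and 2.34 on the log2 scale, were measured at chr15:78809856-78810675, chr6:70371792-70372156, chr15:32265390-32265953, chr4:104957314-104957925 and chr6:40071030-40071473. Around chr15:78809856-78810675, 0 of the 17 other sites within 100 kb were higher and 2 were lower. At chr6:40071030-40071473 the level went from 94.2 ± 6.39 to 419 ± 38.7 reads (SD, n = 2). The rule also named chrX:103481368-103482172, which held 402 and 23.8 reads in wild-type replicates 1 and 2 and 463 and 465 reads in the Hdac3-deleted replicates. Without wild-type replicate 2 its log2 fold change was 0.21 (limma, Benjamini-Hochberg adjusted p = 0.588), so that difference rested on a single library.

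The sites that fell included the largest change of the whole table. At chr1:24612616-24613509 wild-type libraries held 40015 ± 599 normalized reads and Hdac3-deleted libraries 245 ± 127 (SD, n = 2 each), a log2 fold change of -7.45 (limma, Benjamini-Hochberg adjusted p = 1.36e-12). This site had the highest number of reads per base of any site in wild type, 53.6 against a median of 0.412. At chr2:161511279-161512513, with 0 other sites within 100 kb, the level fell from 624 ± 38.7 reads (SD, n = 2) in wild type to 37.0 and 22.6 reads in the 2 Hdac3-deleted libraries (log2 fold change -4.38, limma, Benjamini-Hochberg adjusted p = 1.79e-07). At chr18:44757588-44758265 it fell from 547 ± 6.66 to 62.9 ± 21.3 reads (SD, n = 2; log2 fold change -3.14). At chr7:116701321-116702325 wild type held 1001 ± 178 reads and Hdac3-deleted cells 152 ± 34.2 (SD, n = 2). At chr13:115226778-115227538 the level was 464 ± 99.7 in wild type and 78.6 ± 5.26 in Hdac3-deleted cells (SD, n = 2), while 3 of the 12 other sites within 100 kb were higher and 0 lower. The remaining named sites, at chr11:6020727-6021568, chr9:87084209-87084708, chr4:111455405-111456095, chr5:146596624-146597359 and chr3:147101148-147102172, fell to between 0.154 and 0.194 of the wild-type mean; those on chromosomes 4 and 5 missed the threshold in the DESeq2 Wald test (adjusted p of 0.0678 and 0.0851). At 4 of these 5 sites the SD of the normalized reads was larger in Hdac3-deleted cells than in wild type; at chr4:111455405-111456095 they held 51.0 and 234 reads, against 812 and 742 in wild type.

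**Figure D2:**
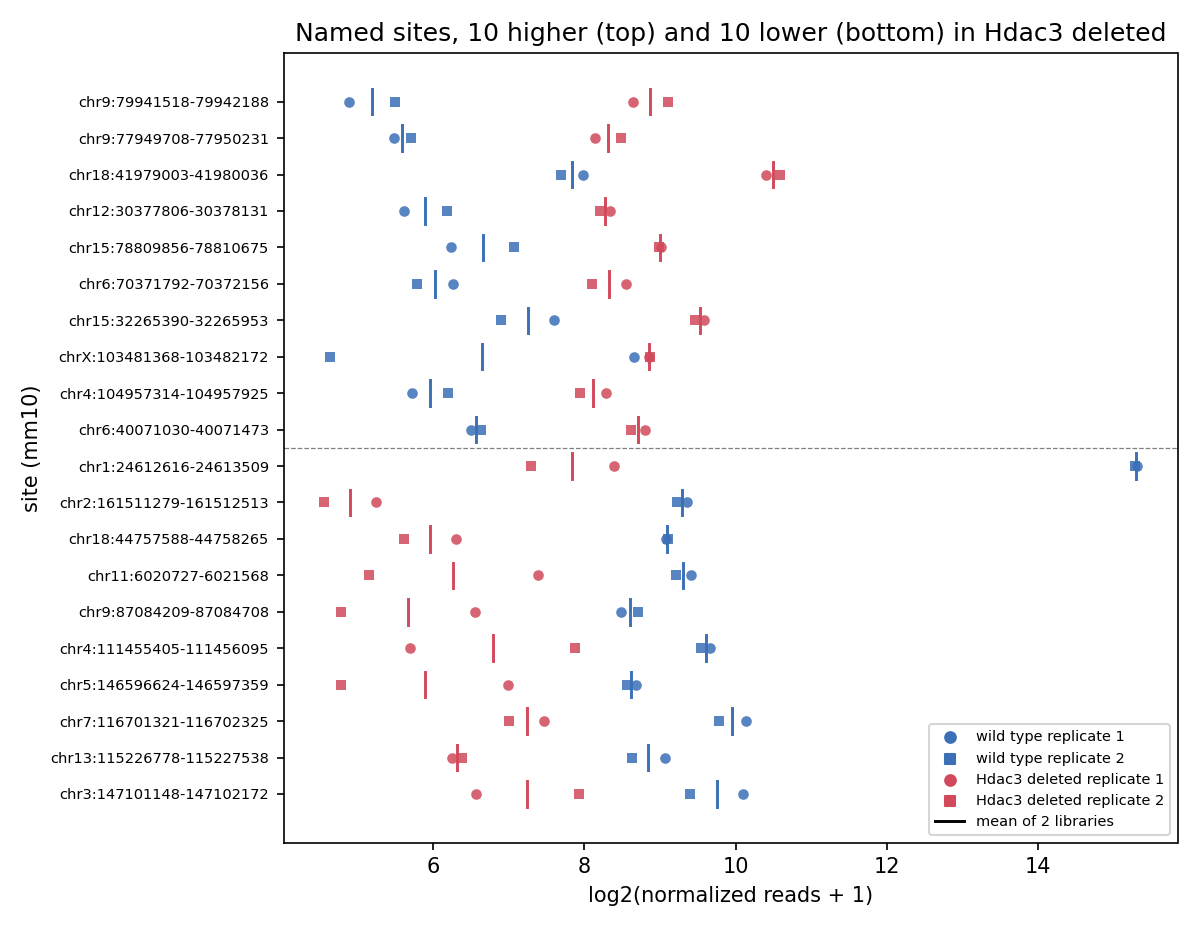
Points show log2(normalized reads + 1) of each library (x axis) at the 20 named sites (y axis, mm10 positions), with wild type in blue and Hdac3 deleted in red and a vertical line at each mean of 2 libraries. As the rule for naming required, both Hdac3-deleted libraries lie on the same side of both wild-type libraries at every named site. Wild-type replicate 2 stands apart from the other 3 libraries at chrX:103481368-103482172.

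Some strongly changed sites lay in blocks that moved one way: 85 (12.9%) of the 660 called sites with a log2 change above 2 in size, while the others lay outside such blocks. On chromosome 12, between 29864965 and 30378131, 10 of 10 sites were higher in Hdac3-deleted cells, with a median log2 fold change of 2.91; the block's mean log2 level was 4.56 ± 0.20 in wild type and 7.46 ± 0.27 in Hdac3-deleted cells (SD, n = 2). On chromosome 4, 5 of 5 sites between 110285443 and 110352033 and 4 of 4 sites between 110588057 and 110673189 were higher, with medians of 3.48 and 2.93. On chromosome 18, 6 of 6 sites between 32930554 and 33065367 and 5 of 5 sites between 47154784 and 47165871 were higher. On chromosome 7, 11 of 11 sites between 116681365 and 117099365 were lower, with a median of -2.88 and mean log2 levels of 7.34 ± 0.16 in wild type and 4.28 ± 0.17 in Hdac3-deleted cells (SD, n = 2). Lower blocks also lay on chromosome 2 (9 of 9 sites between 51589513 and 51768863, 8 of 10 between 52440659 and 52558770), chromosome 5 (8 of 9 between 146585673 and 146637216) and chromosome 9 (4 of 4 between 76320854 and 76365427). A block on chromosome 11, between 114127433 and 114309667, had 8 of 22 sites lower and 14 that did not pass the test, and one on chromosome 3, between 144049699 and 144153561, had 5 of 9 lower. In all, 15 blocks of at least 4 called sites with a log2 change above 2 in size were found, 7 higher and 8 lower. The block on chromosome X, between 50565139 and 50623438, is 1 of the 7: its mean log2 level was 7.65 and 3.43 in wild-type replicates 1 and 2, and 7.63 and 7.83 in Hdac3-deleted replicates 1 and 2, so wild-type replicate 2 alone was low there. Over the genome, 131 pairs of neighbouring strong sites lay within 100 kb of each other, and 94.7% of them moved the same way. The highest share in 10000 shuffles of the directions was 67.2%. The shuffles treat sites as independent, but neighbours can be parts of the same open region, such as those centred at 110.2855 and 110.2861 Mb of chromosome 4. Pairs in the block on chromosome X are counted too. The share therefore does not by itself show that whole regions moved. The definition of a block was chosen after the data were seen.

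**Figure D3:**
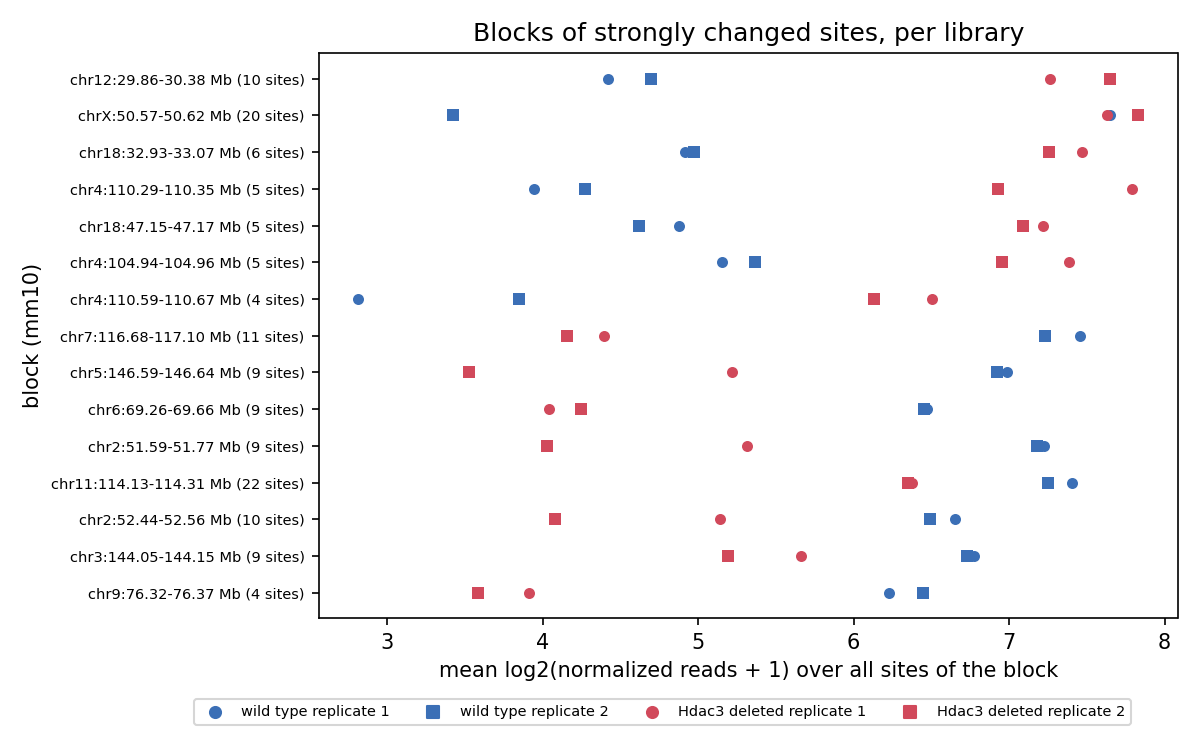
The mean log2(normalized reads + 1) over all sites of each of the 15 blocks (x axis) is drawn per library, wild type in blue and Hdac3 deleted in red, with the 7 higher blocks at the top and the 8 lower blocks below. Genotypes separate in the autosomal blocks, which were chosen from these libraries for such a difference. In the block on chromosome X wild-type replicate 2 lies at 3.43 while the other 3 libraries lie between 7.63 and 7.83.

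The series title concerns V(D)J recombination, the joining of antigen receptor gene segments, so chromosome regions were compared as 1 Mb windows. In the mouse, textbook maps place the immunoglobulin kappa locus on chromosome 6, the heavy chain locus near the distal end of chromosome 12 and the lambda locus on chromosome 16. No mouse gene annotation was used here, so whether a site belongs to these loci was not determined. The window with the largest fall of the 1849 tested was at 69 to 70 Mb of chromosome 6, where 19 of 25 sites were lower and 0 were higher in Hdac3-deleted cells. Its mean log2 level was 6.39 ± 0.04 in wild type and 4.63 ± 0.05 in Hdac3-deleted cells (SD, n = 2; log2 fold change -1.75, limma, Benjamini-Hochberg adjusted p = 0.0153). With the replicate block in the fit this window missed the threshold. In the window before it, at 68 to 69 Mb, 17 of 52 sites were lower and 6 higher (log2 fold change -0.43, limma, Benjamini-Hochberg adjusted p = 0.0253). The window at 70 to 71 Mb held 14 higher and 9 lower sites and did not pass the test, and that at 71 to 72 Mb was higher (log2 fold change 0.45, limma, Benjamini-Hochberg adjusted p = 0.0104). The last 10 windows of chromosome 12, from 110 Mb on, held 50 higher and 47 lower sites among 513, and 1 of the 10 windows passed the test, that at 112 to 113 Mb (log2 fold change -0.20). Their log2 fold changes lay between -0.22 and 0.21. The window of chromosome 6 at 69 to 70 Mb missed the threshold when wild-type replicate 1 or 2 was left out, with log2 fold changes of -1.73 and -1.78 and adjusted p of 0.334 and 0.305 (limma).

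**Figure D4:**
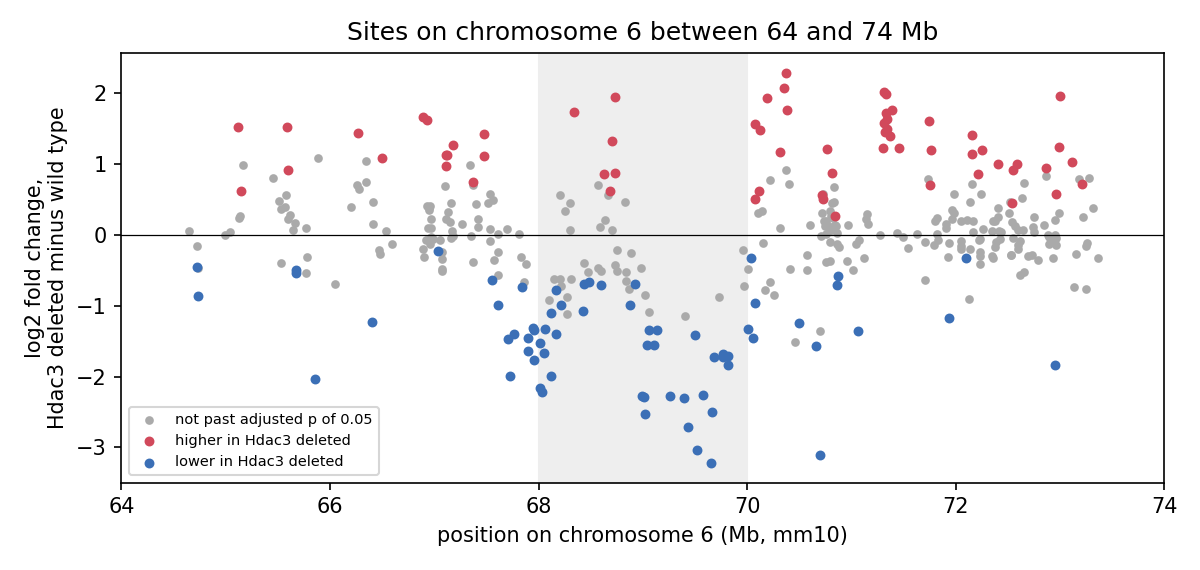
Each point is a site on chromosome 6 between 64 and 74 Mb (x axis, mm10), with its log2 fold change, Hdac3 deleted minus wild type, on the y axis; grey shading marks 68 to 70 Mb. In the shaded part 36 of 77 sites were lower (blue) and 6 were higher (red).

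Of the 1849 windows, 311 were higher and 157 lower in Hdac3-deleted cells. The largest rises were at 47 to 48 Mb of chromosome 11, with 8 of 8 sites higher (log2 fold change 2.18), at 30 to 31 Mb of chromosome 12 (1.92) and at 110 to 111 Mb of chromosome 4 (1.88). Chromosome 16 had a window at 81 to 82 Mb with a log2 fold change of 1.27, and chromosome 18 one at 41 to 42 Mb with 1.19. After the window on chromosome 6 described above, the largest falls were at 138 to 139 Mb of chromosome 6 (-1.16), 87 to 88 Mb of chromosome 9 (-1.12), 56 to 57 Mb of chromosome 1 (-1.04) and 106 to 107 Mb of chromosome 6 (-1.03). In these 4 windows 8 of 11, 4 of 13, 7 of 9 and 10 of 19 sites were called lower. The number of windows past the threshold (limma, Benjamini-Hochberg adjusted p under 0.05, 468 in all) fell to 119 without Hdac3-deleted replicate 1 (57 higher, 62 lower), where the windows named on chromosomes 4 and 16 missed the threshold (adjusted p of 0.0855 and 0.0700, limma), and to 32 (23 higher, 9 lower) when reads were divided by the tags left after filtering.

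By whole chromosome, the chromosomes that carry Hdac3 and the immunoglobulin loci were set beside all sites, of which 11.7% were higher and 8.90% lower. On chromosome 18, 13.3% of 2150 sites were higher and 10.1% lower; on chromosome 12, 13.4% of 2981 sites were higher and 8.59% lower. Chromosome 6 had 12.5% of 4115 sites higher and 8.97% lower, and chromosome 16 had 330 of 2534 sites higher and 188 lower. Chromosome 1 had more lower (11.7%) than higher (11.2%) sites. Of the 12 sites on chromosome Y, 6 were lower and 0 higher; they held 6076 and 3591 reads in wild-type replicates 1 and 2 and 3020 and 1348 in Hdac3-deleted replicates 1 and 2. These are reads before scaling: a read stood for 0.664, 1.13, 0.999 and 1.33 normalized reads in these libraries, in the same order. Scaled in this way, the wild-type replicates held similar levels, above those of both Hdac3-deleted replicates. The labels give no sex of the mice. Of these 12 sites 0 lie below 50 Mb, the part where only wild-type replicate 2 had peaks. Outside that part, wild-type replicate 1 and Hdac3-deleted replicates 1 and 2 still had 14, 11 and 9 peaks on chromosome Y. Levels at these sites therefore need not follow sex, and the likeness of the wild-type replicates says nothing about the sex difference weighed below. The cause was not tested, so these are not read as an effect of genotype. No test between chromosomes was run, so these shares are descriptions.

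Narrow and broad sites differed in the share of their calls that were higher. Among the 27530 sites under 300 bp, 2827 were higher and 1329 lower in Hdac3-deleted cells, so 68.0% of the calls were higher. Among the 6039 sites of 1000 bp or more, 169 were higher and 953 lower, so 15.1% of the calls were higher. The shares differed by Fisher's exact test (two-sided, p = 3.34e-232), in which neighbouring sites are not independent replicates. All sites came from the same libraries, so this p-value does not measure the spread between samples. Broad sites were also the most accessible, with a median of 1190 normalized reads in wild type and 1098 in Hdac3-deleted cells, and their median log2 fold change was -0.09. Without Hdac3-deleted replicate 1, 46.0% of the calls among narrow sites and 18.8% among broad sites were higher, and after removing the trend with abundance by loess the shares were 63.0% and 32.5%. With reads divided by the tags left after filtering, broad sites had 26 higher and 80 lower calls (24.5% higher), against 69.9% higher among the calls of narrow sites.

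**Figure D5:**
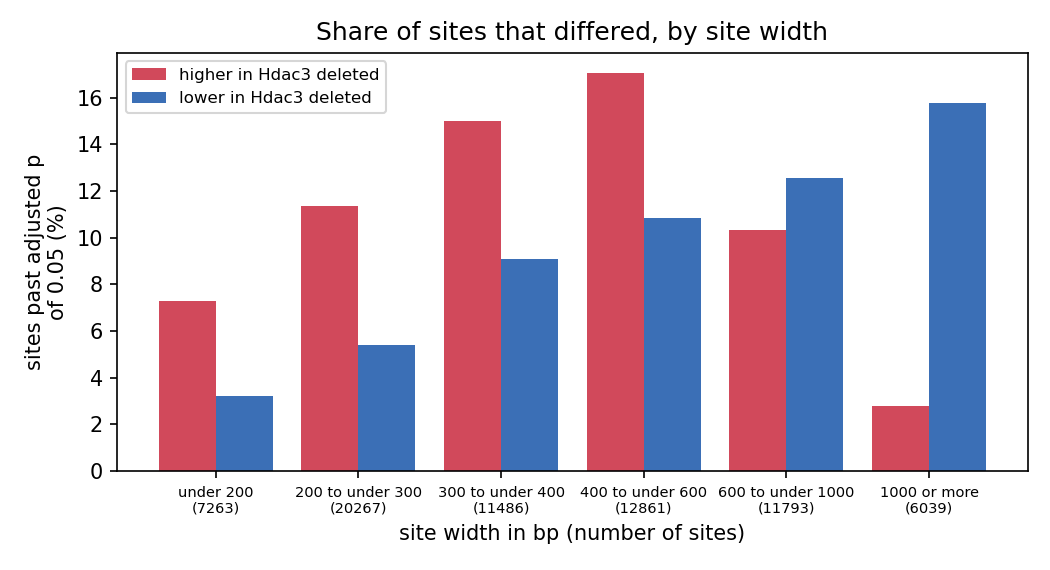
Bars give the percentage of sites called higher (red) or lower (blue) in Hdac3-deleted cells (y axis) in 6 classes of site width (x axis, bp, with the number of sites). In the broadest class 2.80% of the sites were higher and 15.8% were lower, and between 400 and 600 bp 17.1% were higher and 10.9% lower.

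Peak lists called separately in each library were compared next. Wild-type replicates 1 and 2 had 77919 and 65823 peaks, and Hdac3-deleted replicates 1 and 2 had 62140 and 66507. The means, 71871 ± 8553 and 64324 ± 3088 (SD, n = 2), differed by less than the spread between the wild-type libraries, and 2 libraries against 2 cannot reach p under 0.05 in an exact permutation test. The lists covered 31.1, 25.2, 23.7 and 25.2 Mb. A peak in each of the 4 libraries was found at 45614 sites. Another 6165 sites had a peak in both wild-type libraries and in neither Hdac3-deleted library, and 3034 sites had the opposite pattern. The other ways to part the 4 libraries into pairs gave between 338 and 2355 sites. Libraries of one genotype shared more of their peaks: on average 84.9% for the wild-type pair and 86.0% for the Hdac3-deleted pair, against 77.5% to 82.8% for the 4 pairs of different genotype. The Jaccard index of covered bases was 0.705 and 0.718 within genotypes and 0.610 to 0.686 between them. The 4 between-genotype pairs share libraries with each other, so no test was made.

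The authors' own comparison called more sites. An FDR under 0.05 was given to 17497 sites in the authors' deposited table, 10668 higher and 6829 lower in Hdac3-deleted cells. Of the calls made here, 12356 (86.2%) were also calls in the authors' deposited table, 7588 higher and 4768 lower, and 0 had the opposite direction. For the site at chr1:24612616-24613509 the authors' deposited table gives a log2 fold of -7.35. The authors' deposited table gives 3.70 for chr9:79941518-79942188 and 1.12 for chrX:103481368-103482172.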

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

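The tests in this part were chosen after the results were seen, except that of reads per base at the site on chromosome 1 and that of loess on the blocks.

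A signal lay on the part of chromosome Y below 50 Mb, where 0 of the 69709 compared sites lie: wild-type replicate 2 had 10 peaks there, and the other 3 libraries had 0. Of the 28 sites that lay more than 8-fold below each other library in wild-type replicate 2, 27 (96.4%) lay on chromosome X, and 0 such sites lay on chromosome X for any other library. A trace of male cells in a female sample would leave sites of chromosome X near the level of the other libraries, so the 27 sites argue against it as the source of that loss; for the peaks on chromosome Y by themselves it cannot be told apart, because the pileup (50.9% of the highest of that library at the strongest of them) is capped where 1 tag per position is kept. The share of 96.4% is what a library from a male mouse beside 3 from female mice would show, so a difference in sex between the wild-type libraries may account for both signals; the labels give no sex. It would make chromosome X calls such as chrX:103481368-103482172 a matter of sex and not of genotype; 11 of the 27 were called higher in Hdac3-deleted cells, and 1 of them without wild-type replicate 2.

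The fall at chr1:24612616-24613509, from 40015 to 245 normalized reads, was far larger than that of its surroundings. Of the 11 other sites within 100 kb, 4 were called lower and 0 higher, with a median log2 fold change of -0.52 (range -2.41 to 1.04) against -7.45 at the site, which argues against a lost copy of the region as the whole cause. In wild type the site ranked 1 of 69709 by reads per base (rank 46151 in Hdac3-deleted cells), as reads placed there from another near-identical sequence, such as a repeat or a nuclear copy of mitochondrial DNA, might give. A difference in accessibility at the site itself stays open, since the table does not show where else such reads could map.

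The blocks of sites that moved one way were weighed as well. Gain or loss of 1 of 2 copies would move every site of a block by at most 1 on the log2 scale. Since the blocks were chosen by size, each was sought again in 1 library per genotype and measured in the other 2 libraries. Only blocks already found with all libraries were followed, so the measuring libraries had helped to choose them. The block with the most strong sites in each direction, on chromosomes 12 and 7, kept a median of at least 2.68 in size. This was above 1 by more than the SD of its sites. For the other 12 autosomal blocks the smallest median was 0.68 in size, and 8 of 16 measurements exceeded 1 by more than the SD. Because of that choice the medians may be too large, and for these 12 blocks such a copy change cannot be told apart. For the block on chromosome 12 the measured medians were 2.85 and 2.95, and for that on chromosome 7 they were -2.93 and -2.68. The SD of their sites was 0.68 to 0.98. These values argue against such a copy change as the whole cause of those 2 blocks. A strain haplotype carried along with the Hdac3 allele on chromosome 18 would place the blocks there, but 12 of 14 autosomal blocks (85.7%) lay on other chromosomes, which argues against it as the whole cause; for the 2 blocks on chromosome 18 it cannot be told apart, since no alleles were read. A trend of the log ratio with abundance is argued against as the whole cause by the 92.9% of the 85 strong sites in the blocks that stayed past the threshold after loess. A change in the genes of these regions with Hdac3 loss, a shift in the stages within the sorted cells and other strain differences stay open and were not tested.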

How the results depend on the processing

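The scaling to tags, the other pseudocounts, the mean filter, the edgeR fit with TMM factors, the crossed block and the alternatives for windows and for narrow against broad sites were chosen after seeing the data. Against 14335 differential sites, edgeR with TMM factors called 14618 (13982 shared in direction), loess gave 14382 (13134 shared) and the DESeq2 Wald test 11088 (11082 shared). The count fell to 8742 (2958 lower) when scaled to tags after filtering (reads in sites were 46.8, 36.4, 36.6 and 44.0 per 100 such tags in wild-type 1 and 2 and Hdac3-deleted 1 and 2); the cause was not tested. By construction it was 6444 (3802 higher, 2642 lower) at an adjusted p under 0.01 and 8020 (2575 lower) with an absolute log2 fold change of at least 1. With each library left out the counts ranged from 6595 to 14683 (4235 to 7925 higher, 2261 to 6758 lower); the lowest total came without wild-type replicate 1, the deepest library. The replicate block by number gave 14217 sites (deviations of same-numbered libraries correlated at -0.104). With the numbers crossed, which is how the letters A and B in the authors' columns pair the libraries, the block gave 19405 sites and 716 windows. With 2 libraries per genotype, crossing the numbers by construction only turns the sign of that correlation, to 0.104, so it is no separate evidence. The labels do not say what either pairing stands for. Against 468 of 1849 windows, 32 of 1849 passed when scaled to tags after filtering, and 738 of 2811 windows of 0.5 Mb passed; with each library left out the count ranged from 119 to 502, and the cause was not tested. Of the 20 named sites, 17 kept direction and call in the 16 alternatives run and 3 lost the call in 7 fits, with 0 reversals: chrX:103481368-103482172 in 5 fits (adjusted p 0.191 with edgeR), and chr4:111455405-111456095 and chr5:146596624-146597359 with the DESeq2 Wald test (adjusted p 0.0678 and 0.0851). Of the 20 windows with the largest changes, 13 kept their call in 10 alternatives and 7 lost it in at least 1, among them that of chromosome 6 at 69 to 70 Mb with the replicate block (adjusted p 0.108). The difference between narrow and broad sites in the share of calls that were higher (68.0% against 15.1%), in percentage points, ranged from 27.2 to 62.9 with each library left out. The ratio of peak numbers, 0.895, ranged from 0.826 to 0.977 with each library left out, and the gap in peak sharing within against between genotypes, 5.13 percentage points, from 3.56 to 7.28. Gene lists, antigen receptor loci, promoter and distal classes and their alternatives were not run for lack of a mouse annotation.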

Other observations

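The test of matched sites in this part was chosen after the results were seen. On chromosome X, the sites low in wild-type replicate 2 fell into 3 places: 20 between 50549834 and 50623438, 5 between 75734482 and 75758688 and 2 between 103481368 and 103483383. Their median level was 11.3 normalized reads in wild-type replicate 2 and 218 over the other 3 libraries. The other 1473 sites of chromosome X held 2.10%, 2.02%, 2.03% and 2.07% of the reads in wild-type replicates 1 and 2 and Hdac3-deleted replicates 1 and 2.

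The region at 68 to 70 Mb of chromosome 6 is one to look at again, because the kappa light chain locus lies on that chromosome and the series concerns V(D)J recombination. A hypothesis was that its loss in Hdac3-deleted cells may only reflect a general loss of weakly accessible sites. The 77 sites had a median log2 fold change of -0.78, while sites elsewhere, drawn as 10000 random sets matched on the wild-type level, had a median of 0.00815 on the log2 scale, which argues against a general loss at that level. A test laid down before its result was seen, whether the region fell below the lowest of these sets, was set aside because the region was picked for its fall. Mean log2 levels were 6.66 and 6.59 in the wild-type replicates and 5.72 and 5.80 in the Hdac3-deleted replicates, and 55 of the 77 sites were lower in both Hdac3-deleted libraries than in both wild-type libraries. As given above, the window at 69 to 70 Mb missed the threshold with the replicate block. Whether the region coincides with the kappa locus, and whether the stages differed within the B220+CD43+ gate, which leaves out most later precursors, was not tested.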
